A study of Mus musculus and Homo sapiens with 48 samples.

How the data were processed

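RNA was sequenced as directional Illumina libraries made from total RNA, per the labels. The series holds 24 libraries of mouse leukaemia lines and 24 of K562, a human cell line from chronic myelogenous leukaemia, in 8 groups of 3 per species. Groups, doses and days were read from the sample titles. The authors deposited raw read counts per Ensembl gene, 1 table per species, with 37681 mouse and 57195 human genes. Per the submitters' processing notes, CASAVA, STAR 2.4.2a, HTSeq and edgeR were used with genome builds mm9 and hg19. The annotation release, the strand setting of the counting and any filter on reads are not given in the sources used here. Overlapping or antisense genes and near-identical copies, such as the mast cell proteases and the histone genes, are therefore uncertain where the counting could split or drop shared reads.

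Mouse gene symbols were matched by identifier in a table of names: 32642 of 37681 identifiers matched, 14355 of the 14933 tested, which held 98.54% of the mouse counts. Prmt1 had no matched identifier. The annotation at hand was of another build than mm9, so no coordinates are given. No table of names was at hand for the human identifiers, so human gene lists were not tested and at most 2 identifiers per direction are printed.

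Counts were analysed in R 4.3.3. The principal test was the quasi-likelihood F test of edgeR 4.0.16 on the deposited counts of the 24 libraries of a species in 1 model of 8 groups, after filterByExpr with a minimum count of 10 and TMM scaling, with robust dispersion and no block. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, with no minimum fold. It compared each drug and the combination with the control in each genotype, the combination with the sum of both single drugs on the log2 scale (beyond additive), the genotypes without drug, and each drug response between the genotypes. The normalised read count used below is CPM with TMM scaling. Totals per library were 9247240 to 62499100 counts in mouse and 24937484 to 42931344 in K562. Replicates were separate libraries: their counts differed by a chi-square per gene of at least 36 in mouse and 4.27 in K562. The series design text calls the mouse replicates biological. Nothing in the labels says that the 3 K562 replicates came from separate cultures, so K562 p-values measure only the spread between these libraries, which may be technical.

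The mouse replicate names are cell lines, each with a control and 3 treated libraries, so the names pair the libraries. Deviations from the group means correlated at r = 0.806 to 0.960 in the 18 same-line pairs of WT libraries and at r = -0.401 to 0.693 in the 18 of the mutant libraries, across genes; 12 of the WT and 10 of the mutant libraries correlated best with their own line. The biological coefficient of variation was 0.527 without and 0.231 with the line as a block, against 0.121 in K562. In K562 the labels do not say what a shared replicate number marks. Same-numbered control and drug libraries of mutant cells deviated together at r = 0.281, 0.294 and 0.565 for MS023 and at r = 0.240, 0.193 and 0.411 for GSK591, so the count with the replicate block is also given for these comparisons. This was judged per comparison after the counts were seen, and in every other K562 drug comparison with the control at least 1 pair was at r under 0.1. After the data were seen, 1 library was found to stand apart from its line (the library labelled mutant 7 control). Fits without that library and without all 4 libraries of line 7 were added at that point. Unless another fit is named, mouse log2 fold changes are from the edgeR fit with the line as a block and without line 7, over 15081 genes, with n = 3 WT and n = 2 mutant lines and the standard error after ±.

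Gene lists, 24 in number, and the rule for named genes were fixed before the data were examined, as were the comparisons, the test and the alternatives other than those said to be added. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The rule named the 5 genes with the largest rise and the 5 with the largest fall among those that passed. They needed a mean log2 CPM of at least 3, and clone or pseudogene names were left out. The rule asked for the same direction in every line only where a drug was compared with the control. It also named up to 4 members of a list with the smallest p, and a fixed set of PRMT, p53, splicing, leukaemia and survival genes. Since the principal mouse test passed no gene in any drug comparison, the rule was applied in the fits with the line as a block, with all lines and without line 7. With all lines it named genes by size in 2 drug comparisons, GSK591 and the combination in the mutant lines. Some genes that the rule named are not reported here.

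Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, the replicate as a block, and leaving out each replicate in turn. The steps were tested on simulated counts with 200 changed genes. For the WT combination in mouse (14780 genes), the fit without a block recovered 0% of genes changed 1.5-fold, 2.99% of those changed 2-fold and 53.0% of those changed 4-fold; with the block it recovered 8.96%, 46.3% and 95.5%. For the WT combination in K562 (19864 genes) both fits recovered 67.2%, 98.5% and 100%. Unchanged genes called were 0 without and 6 with the block in mouse, and 14 and 13 in K562. The fit behind most mouse values below, blocked by line and without the line whose control stood apart, was not simulated. No comparison in mutant cells was simulated either, so these rates do not describe such fits. On the deposited counts both simulated mouse fits passed 0 genes in the WT combination, so the rates may not carry over to real data. Figures were drawn with matplotlib 3.10.9.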

Results

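Gene expression was measured by RNA sequencing in leukaemia cells treated with inhibitors of protein arginine methyltransferases, enzymes that methylate arginines of splicing factors, histones and other proteins. MS023 inhibits the type I enzymes, which make asymmetric dimethylarginine, and GSK591 inhibits PRMT5, which makes symmetric dimethylarginine. The cells were with or without the P95H mutation of SRSF2, a splicing factor mutated in myeloid leukaemia. The mouse cells were described as 6 primary lines of leukaemia driven by the MLL-AF9 fusion, 3 WT (L, M, N) and 3 Srsf2 mutant (5, 6, 7). They were grown with SCF, IL-3 and IL-6. Each line gave a control, an MS023, a GSK591 and a combination library at day 7. MS023 was used at 100 nM, and GSK591 at 100 nM in WT but 25 nM in mutant lines. The titles do not give the doses of the mouse combination. K562 cells, WT or with the mutation knocked in, were collected at day 8 after DMSO, MS023 at 250 nM, GSK591 at 250 nM or both, with 3 replicates each (L123, L124, L125).

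The mouse lines differed in which myeloid genes they expressed before any drug. Hoxa9 (ENSMUSG00000038227), a homeobox gene that MLL fusions keep active, was at 162 to 177 CPM in the 4 libraries of line M and at most at 0.648 CPM in those of lines L and N. Without drug it was at 140 CPM in mutant line 5 and at 118 CPM in mutant line 6. The MLL-AF9 and haematopoietic stem cell list of 25 genes had a mean log2 CPM of 3.14 in the L and N controls. It was at 6.22 in the M control and at 5.92 and 5.73 in the line 5 and 6 controls. Its share of counts was higher in L and N, at 0.744% and 0.664% against 0.458% in M. The mast cell and basophil list of 13 genes took 5.06% and 5.10% of all counts in the L and N controls and 0.426% in the M control. In the line 5 and line 6 controls it took 2.31% and 1.22%. Lines L and N thus held little Hoxa9 and high mast cell genes, and whether they carried the fusion was not tested. The library labelled mutant 7 control held Hoxa9 at 0.0556 CPM and the mast cell list at 4.56% of counts, against 98.7 to 118 CPM and 1.40% to 1.89% in the 3 drug libraries of line 7. Its log2 CPM correlated across genes with those libraries at r = 0.894 at most. With the combination library of WT line N it correlated at r = 0.987, and with the line N control at r = 0.977. Within the other 5 lines the lowest r was 0.964.

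**Figure D1:**
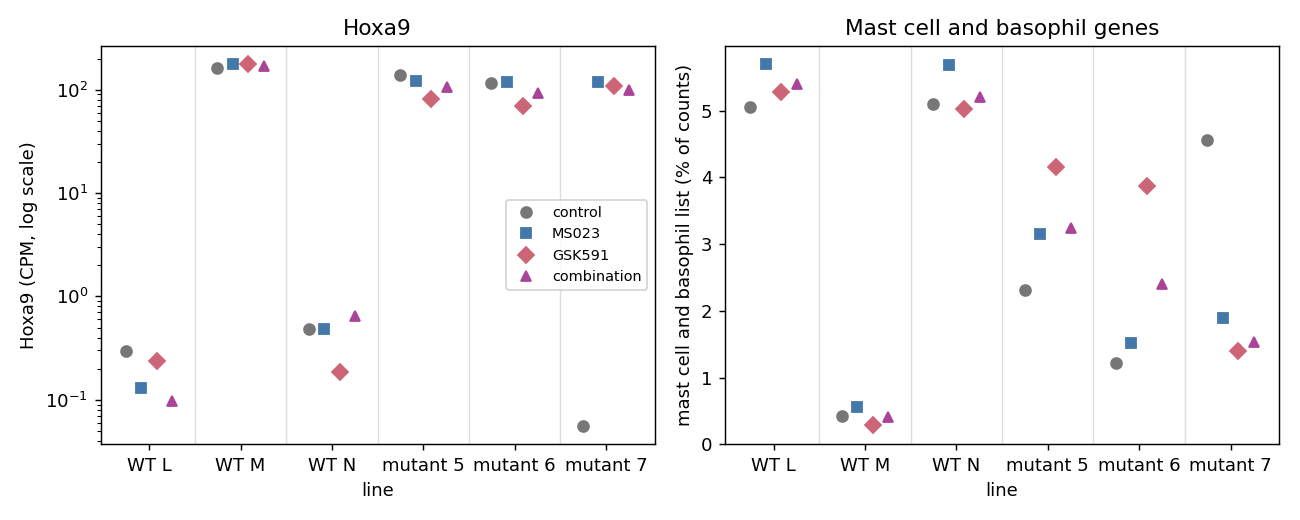
Hoxa9 in CPM on a log scale (left) and the share of all counts taken by the mast cell and basophil list in percent (right), 1 point per mouse library, by line and treatment. The library labelled mutant 7 control (0.0556 CPM, 4.56%) lies with lines L and N and away from the 3 drug libraries of line 7.

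The combination in the WT mouse lines asked what blocking both classes of enzyme does to cells with normal Srsf2. Of these lines, L and N held little Hoxa9 and high mast cell genes, as given above. A response carried by them may therefore not be one of MLL-AF9 leukaemia. Genes of the amino acid response rose. Of the 22 measured genes of the amino acid and ATF4 list, 13 rose and 0 fell (18 adjusted over the list alone), among them Trib3, an ATF4 target (log2 fold change 0.82 ± 0.10), Slc7a5 (0.86 ± 0.12) and Slc3a2 (0.58 ± 0.09), which form a transporter of large amino acids. For this list camera gave an adjusted p = 1.7e-15, and an adjusted p = 0.117 with an estimated correlation. The mean of the list rose by 0.876 in line L and 0.673 in line N but 0.139 in line M. Interferon-stimulated genes fell: 8 of 28 passed and fell (15 adjusted over the list alone), with Irf7, a transcription factor of the interferon response, at -0.96 ± 0.14 and Rsad2 at -1.03 ± 0.21. This list had an adjusted p = 1.8e-08, and an adjusted p = 0.158 with an estimated correlation. Ifih1, a sensor of double-stranded RNA, fell by 0.54.

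Among single genes the largest rises were in Slco2b1, an organic anion transporter (2.48 ± 0.21), the mast cell protease Mcpt2 (2.35 ± 0.35), Calca, which encodes calcitonin and CGRP (1.63 ± 0.21), the fatty acid binding protein Fabp4 (1.56 ± 0.25) and the collagen Col18a1 (1.47 ± 0.22). The largest falls were in Terc, the RNA template of telomerase (-1.66 ± 0.20), Clec5a (-1.16 ± 0.27), the mast cell receptor Mrgprb2 (-1.14 ± 0.16), the protease Prss34 (-1.11 ± 0.29) and the transcription factor Klf2 (-1.11 ± 0.20). Of 26 genes of the MYC and ribosome biogenesis list, 10 rose (13 adjusted over the list alone), such as the nucleolar proteins Ddx21 (0.41 ± 0.08) and Gnl3 (0.42 ± 0.09) and Rrp9 (0.46 ± 0.10). Its adjusted p was 3.2e-08, and the adjusted p = 0.52 with an estimated correlation. Of 28 p53 targets 8 rose and 2 fell (13 and 3 adjusted over the list alone; adjusted p = 0.0032, and adjusted p = 0.158 with an estimated correlation). The mean log2 CPM of the p53 list hardly moved in line N, from 4.949 to 4.958. It went from 4.894 to 5.067 in line L and from 4.192 to 4.446 in line M. The receptor Eda2r rose by 1.76 ± 0.28, Sesn2 by 0.64 ± 0.07, Aen by 0.51 ± 0.08, the pro-apoptotic Bax by 0.42 ± 0.05 and Mdm2, which degrades p53, by 0.38 ± 0.09. Among 12 nonsense-mediated decay factors 4 rose (5 adjusted over the list alone; adjusted p = 0.0108, and adjusted p = 0.41 with an estimated correlation), with Smg5 at 0.34 ± 0.07 and the helicase Upf1 at 0.24 ± 0.07. Among 22 cholesterol synthesis genes 6 rose (7 adjusted over the list alone; adjusted p = 0.00233, and adjusted p = 0.52 with an estimated correlation), with Cyp51 at 0.49 ± 0.11 and Msmo1 at 0.32 ± 0.07. In line M the mean log2 CPM hardly moved, from 5.802 to 5.805 for the cholesterol list and from 5.969 to 6.005 for the decay factors. The cholesterol list went from 5.95 to 6.215 in L and from 6.246 to 6.453 in N. The decay factors went from 6.001 to 6.199 in L and from 6.057 to 6.251 in N. The neutrophil and monocyte list of 34 genes had 6 that fell, including Lcn2 (-0.88 ± 0.18) and S100a8 (-1.01 ± 0.23), and 1 that rose, Itgax (0.77 ± 0.16). Adjusted over the list alone 10 fell and 3 rose (adjusted p = 0.0176, and adjusted p = 0.741 with an estimated correlation). Mast cell genes went both ways, with 4 of 13 up and 2 down, the same counts adjusted over the list alone (adjusted p = 0.493). The tryptase Tpsab1 rose by 2.16 ± 0.37 and Mcpt4 by 1.77 ± 0.38, while Tpsb2, a near-identical tryptase, fell by 1.02.

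In all, 1654 of 15081 genes passed in the WT combination, 915 up and 739 down. This count was 0 without line L, 0 without line N and 2642 without line M, so it rested on lines L and N. The principal edgeR test, with all lines and no block, passed 0 of 14933 genes (368 at an unadjusted p under 0.05, and 2 by DESeq2), and 0 with the block (1613 at an unadjusted p under 0.05). With the block and without only the library labelled mutant 7 control, 1138 passed.

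**Figure D2:**
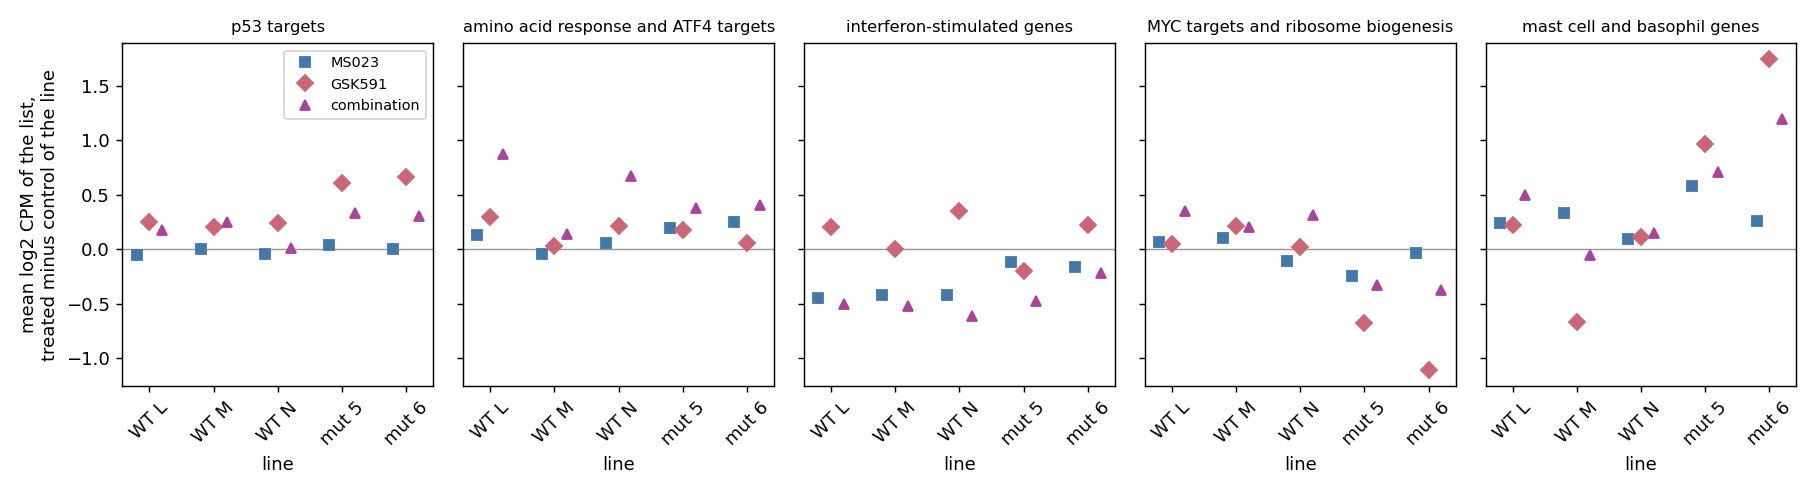
Change in the mean log2 CPM of 5 gene lists, treated minus control library of the same line, 1 point per line and treatment, for WT lines L, M and N and mutant lines 5 and 6 (line 7 is not drawn). The interferon-stimulated list lies below 0 in each of the 5 lines with the combination, by 0.499, 0.519 and 0.611 in L, M and N and by 0.472 and 0.219 in 5 and 6.

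GSK591 alone in the WT lines raised p53 targets. Bax rose by 0.41 ± 0.05 (adjusted p = 0.016) and Ccng1, a p53-induced cyclin, by 0.40 ± 0.07 (adjusted p = 0.0397), the 2 of 28 measured targets that passed over all genes. Adjusted over the list alone, 13 passed and rose. Camera gave an adjusted p = 2.6e-10 and an adjusted p = 0.0075 with an estimated correlation. The mean of the list rose in 3 of 3 lines, by 0.252 in L, 0.202 in M and 0.240 in N. Scd1, a desaturase that makes monounsaturated fatty acids, fell by 1.41 on the log2 scale (SE 0.25). The other large rises were in the elastase Mmp12 (0.98 ± 0.17), Adamts10 (0.77 ± 0.11), Enpp1 (0.73 ± 0.13), the RNA methyltransferase Mettl16 (0.69 ± 0.12) and Sh3pxd2a (0.63 ± 0.12). The other falls were in the small nuclear RNA of the Cajal body Scarna13 (-0.55 ± 0.09), Amdhd2 (-0.45 ± 0.07), Tsc22d3 (-0.43 ± 0.08) and Stx16 (-0.38 ± 0.06). In all 33 genes passed, 23 up and 10 down. The count was 0 without line L or without line N, 4 without line 5 or without line 6, 11 without only the library labelled mutant 7 control, and 235 by DESeq2. The principal edgeR test passed 0 genes (93 at an unadjusted p under 0.05, and 1 by DESeq2), and 0 with the block (590 at an unadjusted p under 0.05).

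MS023 alone in the WT lines lowered myeloid genes and genes of the interferon response. Bst1 (-1.39 ± 0.22), the complement component C3 (-1.23 ± 0.18), Lbp, which binds lipopolysaccharide (-1.11 ± 0.18), and the neutrophil granule protein Lcn2 (-1.04 ± 0.18) were among the largest falls, and Calca rose by 1.18 ± 0.21. Of 34 neutrophil and monocyte genes 1 passed and fell over all genes, but 15 fell adjusted over the list alone (adjusted p = 1.6e-15, and adjusted p = 0.181 with an estimated correlation), with list means of -0.701, -0.529 and -0.083 in L, M and N. The azurophil granule list of 12 genes also had a lower mean log2 CPM with MS023, by little in line M. It was at 3.79, 5.79 and 4.83 in L, M and N against 4.71, 5.85 and 5.41 without drug. With GSK591 it was lower too, at 4.098, 5.698 and 4.773. In mutant lines 5 and 6 the azurophil list was higher with MS023, at 6.172 and 5.755 against 5.999 and 5.392 without drug. The neutrophil and monocyte list was also higher there, at 5.319 and 4.937 against 5.175 and 4.526. Of 28 interferon-stimulated genes 1, Ifih1 (-0.62 ± 0.10), passed and fell over all genes and 6 fell adjusted over the list alone (adjusted p = 2.4e-10, and adjusted p = 0.181 with an estimated correlation), with list means of -0.45, -0.417 and -0.416. In all 22 genes passed, 2 up and 20 down. The count was 0 without line L, 8 without line M, 2 without line 5 or without line 6, 0 without only the library labelled mutant 7 control, and 167 by DESeq2. The principal edgeR test passed 0 genes (43 at an unadjusted p under 0.05, and 0 by DESeq2), and 0 with the block (324 at an unadjusted p under 0.05).

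GSK591 at 25 nM raised mast cell genes and p53 targets in mutant mouse lines 5 and 6, and lowered genes of ribosome biogenesis and cell division. Of 13 mast cell genes 11 rose, over all genes and adjusted over the list alone, among them the serine protease Gzmb (1.94 ± 0.27), Fcer1a, a chain of the IgE receptor (1.36 ± 0.19), the carboxypeptidase Cpa3 (1.31 ± 0.21) and the mast cell transcription factor Mitf (0.95 ± 0.15). The list went from 2.31% to 4.16% of counts in line 5 and from 1.22% to 3.87% in line 6, while Hoxa9 fell by 0.77 (SE 0.13) and Kit, the SCF receptor, rose by 1.20 ± 0.20. Camera gave an adjusted p = 3.5e-06, and an adjusted p = 0.368 with an estimated correlation. Among 28 p53 targets 16 rose and 4 fell, over all genes and over the list alone, including Eda2r (2.92 ± 0.32), the stress cytokine Gdf15 (2.18 ± 0.14), the cell cycle inhibitor Cdkn1a (1.69 ± 0.19), the pro-apoptotic Bbc3 (1.13 ± 0.10), Sesn2 (0.91 ± 0.09), Mdm2 (0.82 ± 0.11) and Mdm4 (0.35 ± 0.10). The p53 list had an adjusted p = 1.2e-06, and an adjusted p = 0.0504 with an estimated correlation. These rises came with the larger share of mast cell transcripts just given. In line 7 the mean log2 CPM of the p53 list was 4.892 with GSK591, 4.837 with MS023 and 4.887 with the combination. In lines 5 and 6 it was 5.225 and 5.176 with GSK591 against 4.653 and 4.51 with MS023. The p53 list's share of counts in line 7 was 0.213% with GSK591 against 0.186% with MS023. With all 3 mutant lines kept, the log2 fold changes of Mcpt2, Slco2b1, Bbc3, Sesn2 and Gzmb were below 0 with and without the block, as were those of Eda2r without it (-0.22) and Mitf with it (-0.091), while Hoxa9 was at 0.0059 without and 0.23 with the block. Camera then gave the mast cell list the opposite direction (adjusted p = 0.559 without and 0.901 with the block).

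Ribosome biogenesis and MYC target genes fell with GSK591 in the mutant lines: 25 of 26 passed (26 adjusted over the list alone), with Cad, an enzyme of pyrimidine synthesis, at -1.45 ± 0.16, Nop56 at -1.42 ± 0.14 and Dkc1 at -1.32 ± 0.13 (adjusted p = 2.1e-16, and adjusted p = 0.368 with an estimated correlation). Myc itself was at -0.84 ± 0.21. Of 32 DNA replication genes 29 fell and 1 rose, over all genes and over the list alone, with Cdt1 at -1.43 ± 0.20 and the helicase subunit Mcm2 at -1.38 ± 0.20 (adjusted p = 2.1e-12, and adjusted p = 0.368 with an estimated correlation). Of 28 mitotic genes 24 fell (25 adjusted over the list alone), with cyclin Ccnb1 at -1.42 ± 0.28 and the kinase Aurkb at -1.39 ± 0.28 (adjusted p = 1.2e-06, and adjusted p = 0.466 with an estimated correlation). Of 17 histone genes 15 fell (16 adjusted over the list alone), with Hist2h2ac at -0.82 ± 0.12 (adjusted p = 1.2e-06, and adjusted p = 0.368 with an estimated correlation). Among 15 Sm and LSm proteins, the core of spliceosomal snRNPs, 13 fell over all genes and over the list alone, with Snrpf at -0.87 ± 0.13 and Snrpd1 at -0.76 ± 0.13 (adjusted p = 4.0e-05, and adjusted p = 0.368 with an estimated correlation). Among 23 hnRNPs and FET proteins 14 fell and 2 rose (14 and 3 adjusted over the list alone), with Hnrnpa1 at -0.66 ± 0.12 (adjusted p = 0.0161, and adjusted p = 0.466 with an estimated correlation). The methyltransferases fell too, 7 of 11 with 2 that rose, over all genes and over the list alone (adjusted p = 0.0108, and adjusted p = 0.368 with an estimated correlation). Prmt5, the target of the drug, fell by 1.15 (SE 0.14), Prmt7 by 1.12 (SE 0.13), Carm1 by 0.37 (SE 0.07) and Prmt6 by 0.35 (SE 0.11). Srsf2 fell by 0.41 (SE 0.08) and Ezh2 by 0.38 (SE 0.10), while the survival gene Mcl1 rose by 0.67 ± 0.10. In the same libraries the mast cell list went from 2.31% to 4.16% of counts in line 5 and from 1.22% to 3.87% in line 6. Among the WT controls, the mean log2 CPM in lines L and N, where mast cell genes were high, was 5.66 and 6.09 for the MYC list against 7.145 in line M, 4.27 and 5.13 against 5.98 for DNA replication, and 3.94 and 5.885 against 6.18 for mitosis. In line 7 the GSK591 library was at 6.81 for the MYC list and 5.81 for DNA replication. The library labelled mutant 7 control, which stood apart from that line, was lower, at 6.72 and 5.07. The MS023 library of line 7 was higher, at 6.86 and 6.035.

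By size alone, Mcpt2 (3.01 ± 0.40), Egr2 (2.98 ± 0.36), the oxysterol receptor Gpr183 (2.77 ± 0.51), the phosphatase Dusp4 (2.76 ± 0.34) and Slco2b1 (2.74 ± 0.24) rose most with GSK591 in the mutant lines. Neutrophil elastase Elane (-2.21 ± 0.38), Nkg7 (-2.12 ± 0.43), Scd1 (-2.00 ± 0.42), the granule protein Prss57 (-1.99 ± 0.31) and Cth (-1.99 ± 0.31) fell most. With all 3 mutant lines and no block, Elane was at 0.019 and Prss57 at 0.64. With the block and all 3 lines, the genes that moved alike in 3 of 3 lines and rose most were the lectin receptor Clec4n (1.72 ± 0.34), fibrillin Fbn1 (1.61 ± 0.37), the macrophage receptor Trem2 (1.495 ± 0.27), Pira2 (1.49 ± 0.31) and Arhgap24 (1.48 ± 0.24). Scd1 (-2.72 ± 0.59), Galnt3 (-1.49 ± 0.34), the desaturase Fads2 (-1.46 ± 0.15), Angptl4 (-1.30 ± 0.32) and Usp6nl (-1.13 ± 0.24) fell most, and these 10 genes passed in the same direction without line 7. In line 7 the change was taken against the library labelled mutant 7 control, which stood apart from that line. Agreement in line 7 may therefore be a difference between lines rather than a drug effect. In all 7061 genes passed, 3552 up and 3509 down, with 1698 without line 6. The principal edgeR test passed 0 genes with all lines and no block (796 at an unadjusted p under 0.05, and 57 by DESeq2) and 1 without line 7. With the block and all 3 lines it passed 548, 225 up and 323 down, among them Scd1, Carm1, Srsf2, Ezh2, Hnrnpa1 and Hist2h2ac but not Prmt5 (-0.66 ± 0.23, adjusted p = 0.121).

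The combination in the mutant lines raised stromal, mast cell and stress genes. Of 11 measured stromal and endothelial genes 8 rose, over all genes and over the list alone, with fibronectin Fn1 at 3.27 ± 0.50, the collagen Col1a2 at 2.43 ± 0.39, Tagln at 1.75 ± 0.34 and vimentin Vim at 0.80 ± 0.15 (adjusted p = 9.2e-06, and adjusted p = 0.0573 with an estimated correlation). Col1a2 itself was scarce, at 7.62 and 5.85 CPM with the combination in lines 5 and 6 against 0.965 and 1.65 CPM without drug. Of 13 mast cell genes 6 rose (11 adjusted over the list alone), with Mcpt4 at 2.57 ± 0.41 and Gzmb at 1.70 ± 0.27 (adjusted p = 1.7e-05, and adjusted p = 0.618 with an estimated correlation). The list reached 3.24% and 2.41% of counts in lines 5 and 6. Of 22 amino acid and ATF4 genes 10 rose (12 rose and 1 fell adjusted over the list alone), with Trib3 at 0.85 ± 0.12, Slc3a2 at 0.72 ± 0.11 and Ddit4, an inhibitor of mTORC1, at 0.68 ± 0.09 (adjusted p = 0.00013, and adjusted p = 0.618 with an estimated correlation). Of 28 p53 targets 11 rose and 1 fell, over all genes and over the list alone, with Gdf15 at 1.10 ± 0.14, Cdkn1a at 1.0 ± 0.19 and Bbc3 at 0.59 ± 0.10 (adjusted p = 0.00027, and adjusted p = 0.119 with an estimated correlation). Of 26 MYC and ribosome biogenesis genes 10 fell (17 adjusted over the list alone), with Nop56 at -0.84 ± 0.14 and Cad at -0.74 ± 0.15 (adjusted p = 6.1e-06, and adjusted p = 0.667 with an estimated correlation). Of 28 interferon-stimulated genes 4 fell and 1 rose, over all genes and over the list alone, with Irf7 at -0.75 ± 0.16 and Oas3 at -1.15 ± 0.24 (adjusted p = 0.00114, and adjusted p = 0.618 with an estimated correlation). Prmt5 fell by 0.60 (SE 0.13) and Kit rose by 0.77 ± 0.20.

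The genes that rose most with the combination in the mutant lines were Mcpt2 (4.04 ± 0.41), Fn1, Gpr183 (3.10 ± 0.50), Egr2 (2.93 ± 0.35) and the plasminogen activator inhibitor Serpinb2 (2.91 ± 0.24). Among those that fell most were Terc (-2.11 ± 0.23), the immunoglobulin chain Ighm (-1.89 ± 0.21), Thbs1 (-1.70 ± 0.30) and the integrin Itga1 (-1.67 ± 0.18). In all 2697 genes passed, 1496 up and 1201 down, with 753 without line 5 and 296 without line 6. The principal edgeR test passed 0 genes (523 at an unadjusted p under 0.05, and 13 by DESeq2). With the block and all 3 lines it passed 86, 59 up and 27 down. Among those that moved alike in 3 of 3 lines, the tyrosine kinase Fgr (1.77 ± 0.25), Pid1 (1.43 ± 0.27), Clec4a2 (1.42 ± 0.29, against 0.92 without line 7), March1 (1.37 ± 0.25) and Btnl9 (1.34 ± 0.23) rose most. Fads2 (-1.37 ± 0.15), Bhlhb9 (-0.94 ± 0.19), the beta-galactosidase Glb1 (-0.82 ± 0.13), Igsf8 (-0.80 ± 0.13) and Pyurf (-0.70 ± 0.14) fell most, and these 10 genes passed in the same direction without line 7. Line 7 was again measured against the library labelled mutant 7 control, so agreement in that line may not be a drug effect. In the fit with all 3 lines Mcpt2, Serpinb2, Bbc3, Trib3, Slc3a2, Gzmb, Vim, Cdkn1a and Kit had log2 fold changes below 0, as they did without the block, where Mcpt4 was at -0.47. Camera turned the direction of 3 lists with line 7 kept, with adjusted p without and with the block of 0.186 and 0.163 for the mast cell list, 0.152 and 0.229 for the amino acid and ATF4 list and 0.156 and 0.229 for the interferon-stimulated list.

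**Figure D3:**
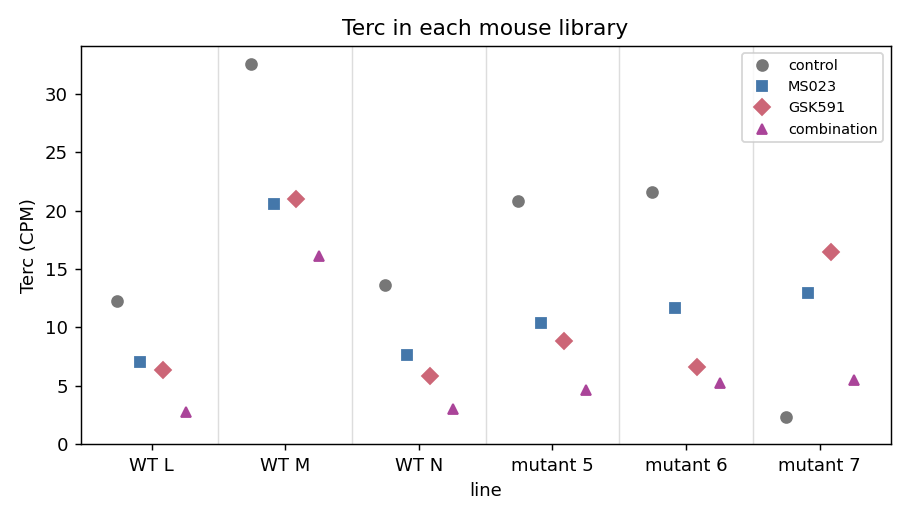
Terc, the telomerase RNA, in CPM, 1 point per mouse library, by line and treatment. The combination library was the lowest of its line in each of lines L, M, N, 5 and 6 (2.76, 16.1, 3.0, 4.61 and 5.25 CPM against 12.3, 32.6, 13.6, 20.9 and 21.6 CPM without drug). The library labelled mutant 7 control was at 2.33 CPM.

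MS023 alone in the mutant lines moved few genes. Upp1, a uridine phosphorylase, rose by 1.39 ± 0.24, the motor protein Myo6 by 0.77 ± 0.11, Tspoap1 by 0.65 ± 0.11 and Fbxl2 by 0.64 ± 0.10. Itga1 (-1.37 ± 0.17), Ighm (-1.20 ± 0.20), the histone variant H2afj (-0.88 ± 0.11) and Dnajc6 (-0.80 ± 0.14) were among those that fell most. With all 3 mutant lines Upp1 was at -1.13 without and -0.85 with the block, and Dnajc6 at 0.22 without a block. Of 22 amino acid and ATF4 genes 0 passed over all genes, but 7 rose adjusted over the list alone (adjusted p = 1.2e-05, and adjusted p = 0.859 with an estimated correlation). With all 3 mutant lines this list pointed down (adjusted p = 0.0026 without and 0.0038 with the block). In all 18 genes passed, 6 up and 12 down, with 3 without line L, 33 without line M, 0 without line N, 5 or 6, and 141 by DESeq2. The principal edgeR test passed 0 genes (258 at an unadjusted p under 0.05, and 1 by DESeq2), and 1 with the block, Mfhas1 (-1.04 ± 0.14), named after its value was seen.

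Comparing the combination with the sum of both single drugs asked whether they add up on the log2 scale. In the WT mouse lines edgeR passed 0 genes beyond additivity without line 7 (541 at an unadjusted p under 0.05, and 2 by DESeq2) and 0 in the principal test (21 at an unadjusted p under 0.05, and 0 by DESeq2). In the mutant lines 590 passed without line 7, 342 above and 248 below the sum. The desmosomal protein Dsp (1.84 ± 0.27), Cth (1.74 ± 0.42), Prss57 (1.74 ± 0.43), Sh2d5 (1.64 ± 0.26) and the adhesion molecule Ncam1 (1.61 ± 0.34) lay above the sum, and Col18a1 (-1.88 ± 0.46), H2-Q10 (-1.58 ± 0.32), Styk1 (-1.46 ± 0.32), Aqp9 (-1.44 ± 0.24) and Slco2b1 (-1.41 ± 0.32) below it. With all lines, without and with the block, Slco2b1 (3.10 and 2.48), Col18a1 (1.60 and 0.39), Styk1 (0.77 and 0.73) and Aqp9 (0.66 and 0.48) lay above the sum, and Prss57 lay below it without a block (-0.83). The doses of the combination are not given, so departure from the sum can also hold a difference in dose. The count was 0 without line L or without line N, 162 without line 5, 1 without line 6, 366 with no filter on low counts, 2018 by DESeq2 and 0 without only the library labelled mutant 7 control. The principal edgeR test passed 0 (178 at an unadjusted p under 0.05, and 2 by DESeq2), and 0 with the block (1155 at an unadjusted p under 0.05).

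Without drug, 5 genes differed between mutant and WT mouse lines in the principal test, 4 higher and 1 lower in mutant. Fnbp1l, which links membranes to actin, was higher by a log2 fold change of 4.98 ± 0.85 (adjusted p = 0.044), at 137 and 253 CPM in lines 5 and 6 against 1.95 to 5.58 CPM in the 3 WT controls. The library labelled mutant 7 control was at 10.6 CPM and the drug libraries of line 7 at 174 to 191 CPM. The phosphodiesterase Pde8a was higher by 1.59 ± 0.24 (adjusted p = 0.027) and Lilra6, a myeloid receptor, lower at -2.60 ± 0.37 (adjusted p = 0.0245). Schip1 (4.72 ± 0.79) and Cc2d2a (4.45 ± 0.74), both with an adjusted p = 0.044, complete the 5 and were named after their values were seen, being less abundant than the rule asked. The count was 2 with no filter on low counts, 309 by DESeq2, 358 without the library labelled mutant 7 control, 317 without all of line 7, 2686 without line M, and 0 without line L, N, 5 or 6 (1501 genes were at an unadjusted p under 0.05 in the principal test). The 3 WT lines did not share the Hoxa9 and mast cell levels given above, so the genotypes were compared across lines that differed in these genes too.

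Drug responses were compared between the genotypes by their difference in log2 fold change. GSK591 responses differed at 5139 genes without line 7, 2586 higher and 2553 lower in mutant, at a dose of 25 nM in mutant against 100 nM in WT lines. WT lines L and N also differed from the mutant lines in Hoxa9 and mast cell genes before any drug. Genotype, dose and kind of cell therefore cannot be told apart here. The highest differences were 2.70 ± 0.47 for Egr2, 2.20 ± 0.48 for Nr4a1, 2.10 ± 0.29 for Cd69, 2.07 ± 0.50 for Mycn and 2.05 ± 0.44 for Dusp4. The lowest were Cth (-2.52 ± 0.51), the neurofilament Nefh (-2.04 ± 0.47), Cdca7 (-1.93 ± 0.26), the cytokine subunit Il12a (-1.89 ± 0.25) and Hist1h2ah (-1.88 ± 0.48). The combination responses differed at 495 genes, 206 higher and 289 lower in mutant. Differences were highest for Fn1 (2.81 ± 0.63), the calprotectin subunit S100a8 (2.81 ± 0.37), Egr2 (2.69 ± 0.47), Serpinb2 (2.69 ± 0.30) and Nr4a1 (2.26 ± 0.49) and lowest for Il12a (-1.82 ± 0.25), Clec2i (-1.64 ± 0.31), Ighm (-1.62 ± 0.29), Angptl4 (-1.60 ± 0.40) and Prrg4 (-1.55 ± 0.30). With all lines, the difference in GSK591 response was -1.44 without and -1.09 with the block for Mycn and -0.12 without a block for Dusp4, and that in combination response was -1.16 and -0.92 for Serpinb2. The MS023 responses differed at 1 gene, Heg1 (-0.76 ± 0.10), and at 72 by DESeq2. The GSK591 count was 815 without line 6. The combination count was 4 without line L, 1222 without line M, 8 without line N, 232 without line 5, 3 without line 6 and 1553 by DESeq2. The MS023 count was 0 without line L, M, 5 or 6, 29 without line N and 0 with RLE size factors. Without only the library labelled mutant 7 control the counts were 2633, 104 and 1. In the principal edgeR test they were 0, 0 and 0 for GSK591, the combination and MS023 (365, 535 and about 1.2e+02 at an unadjusted p under 0.05; 2, 6 and 1 by DESeq2), and 0 in each with the block.

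Of the genes followed in every mouse comparison whatever their change, Meis1, Itgam and Bcl2 passed in none of the 6 drug comparisons without line 7. Hoxa9, Kit, Myc, Ezh2, Mcl1, Cdkn1a, Mdm4, Srsf2, Prmt5 and Carm1 passed in no WT comparison. Hoxa9 was barely expressed in WT lines L and N, as given above, so its lack of a call there says little. Ints3, a subunit of Integrator, passed with the combination in the mutant lines, at -0.24 (adjusted p = 0.0278), and was at -0.17 (adjusted p = 0.0687) in the WT lines. Prmt6 rose with the combination in the WT lines by 0.40 ± 0.09 and fell with GSK591 in the mutant lines.

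Between the genotypes, mouse log2 fold changes of a drug were set side by side across the 9470 genes with a mean log2 CPM of at least 3, which share no library but are not independent replicates. Without line 7, Pearson's r was 0.26 for MS023, 0.0745 for GSK591 and 0.279 for the combination, and Spearman's rho 0.328, -0.0479 and 0.194. Over all genes r was 0.149, 0.127 and 0.272. Of the genes that rose with the combination, 260 rose in both genotypes where independent lists would share 90.8, and 205 fell in both where they would share 58.9; 14 rose in WT and fell in mutant and 14 the reverse. In the principal fit with line 7, r was -0.255, 0.0202 and -0.227 over the 9485 genes at that level, and -0.0735, 0.0766 and -0.0446 over all 14933.

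In K562 cells the combination changed more genes than either drug. In WT cells 8722 of 20316 genes passed, 4149 up and 4573 down, against 403 (146 up, 257 down) with MS023 and 1229 (582 up, 647 down) with GSK591. In mutant cells 6985 passed with the combination (3233 up, 3752 down), 75 with MS023 (9 up, 66 down) and 1404 with GSK591 (608 up, 796 down). No gene names were at hand for these identifiers. ENSG00000004939 rose with the combination from 11.5 ± 2.01 to 125.1 ± 17.7 CPM in WT cells (SD, n = 3; log2 fold change 3.45 ± 0.22) and from 10.5 ± 1.65 to 83.4 ± 0.584 CPM in mutant cells (2.99 ± 0.22), while MS023 alone left it at 10.4 CPM and GSK591 at 16.3 CPM in WT cells. ENSG00000169877 rose by 3.31 ± 0.24 in WT and 2.82 ± 0.24 in mutant cells. ENSG00000017427 fell from 28.5 ± 7.95 to 0.363 ± 0.0374 CPM in WT cells (-6.28 ± 0.47) and from 48.3 ± 5.79 to 3.0 ± 2.04 CPM in mutant cells (-3.94 ± 0.36), with 8.66 CPM under MS023 and 5.07 CPM under GSK591 in WT cells. ENSG00000139269 fell in WT cells (-5.22 ± 0.81) and in mutant cells (-4.64 ± 0.78).

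Leaving out 1 replicate moved many of the K562 counts by more than 1.5 times. Where this raised a count given next, the replicate left out was mutant L125, also for WT cells, which shared 1 model with mutant cells. The mutant L125 control correlated at r = 0.9837 and 0.9843 with the mutant L123 and L124 controls, which correlated at r = 0.9922. For the combination libraries these values were 0.9905, 0.9901 and 0.9907. The MS023 count in WT cells was 24, 89 and 150 without WT L123, L124 and L125, 243 without mutant L124 and 1396 without mutant L125; it was 707 with no filter on low counts and 907 by DESeq2. The GSK591 count in WT cells was 128, 484 and 388 without WT L123, L124 and L125 and 2394 without mutant L125. In mutant cells the MS023 count was 8, 15 and 166 and the GSK591 count 114, 101 and 3107 without mutant L123, L124 and L125. The combination count in mutant cells was 4243 without mutant L123 and 4090 without mutant L124. MS023 in mutant cells gave 320 with no filter, 246 by DESeq2 and 178 with the replicate block, and GSK591 in mutant cells gave 2131 with the block.

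**Figure D4:**
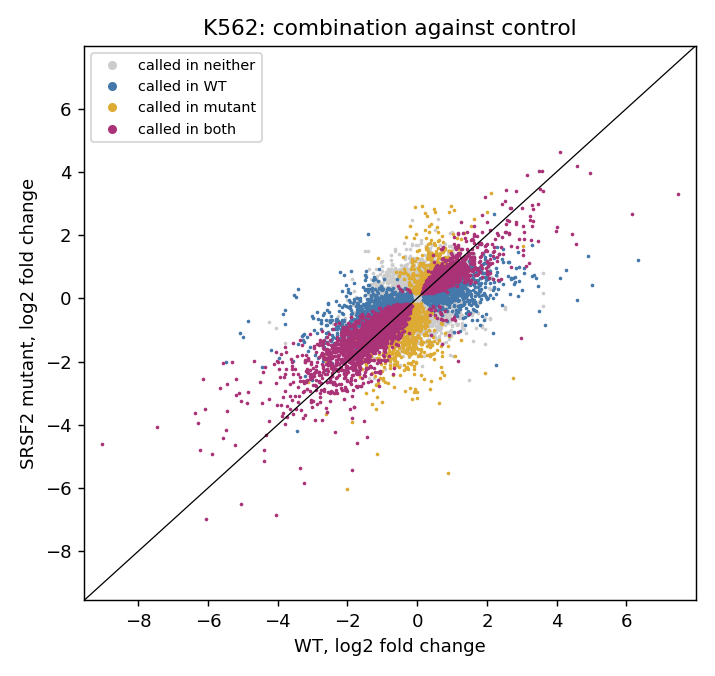
Log2 fold change of the combination against control in WT K562 cells (horizontal) and SRSF2 mutant K562 cells (vertical), 1 point per gene, coloured by the genotypes in which it passed; the line marks equal change. Across these 20316 genes r was 0.736.

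The log2 fold changes of WT and mutant K562 cells, which share no library, correlated across genes, with Pearson's r of 0.377 for MS023, 0.431 for GSK591 and 0.736 for the combination over 20316 genes, and 0.731, 0.686 and 0.907 over the 10027 genes with a mean log2 CPM of at least 3. With the combination 2573 genes rose in both genotypes (660.3 for independent lists) and 2888 fell in both (844.6), while 28 rose in WT and fell in mutant cells and 6 the reverse. With GSK591 282 genes rose in both (17.4) and 313 fell in both (25.4), and with MS023 6 rose in both (0.0647) and 47 fell in both (0.835).

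The K562 combination departed from the sum of the single drugs at 2245 genes in WT cells, 935 above and 1310 below, and at 287 in mutant cells, 55 above and 232 below. The WT count was 670, 407 and 731 without WT L123, L124 and L125 and 4381 without mutant L125. The mutant count was 43, 18 and 504 without mutant L123, L124 and L125 and 185 without WT L123, and 609 with no filter and 577 by DESeq2. The departure itself differed between the genotypes at 1 gene (1680 at an unadjusted p under 0.05), and at 75 without mutant L125; this contrast was added after the data were seen.

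Without drug, 4168 genes differed between mutant and WT K562 cells, 2176 higher and 1992 lower in mutant. The response to the combination differed at 224 genes, 92 higher and 132 lower in mutant; this count was 20, 67 and 63 without WT L123, L124 and L125, 83 and 62 without mutant L123 and L124, 523 with no filter and 451 by DESeq2. For MS023 and GSK591 edgeR found 0 genes with a different response (469 and 980 at an unadjusted p under 0.05; 3 and 4 by DESeq2; 7 and about 1.3e+02 with no filter), and 2 and 67 without mutant L125.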

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

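The tests of the 3 patterns weighed here, the contrast of additivity between the K562 genotypes, and the splits of fits with the line as a block were chosen only after the results were seen, while the other splits were planned. Drug effects that differed between the genotypes were singled out by the test of the difference itself. The response to the combination differed between WT and mutant K562 cells at 224 genes, and the departure from additivity at 1 gene. In mouse without line 7, the GSK591 responses differed at 5139 genes, the combination responses at 495 and the MS023 responses at 1, with another GSK591 dose in each genotype and only 2 mutant lines. WT lines L and N also differed from the mutant lines in Hoxa9 and mast cell genes before any drug.

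The library labelled mutant 7 control stood apart from its line, with Hoxa9 at 0.0556 CPM and mast cell genes at 4.56% of counts. A partial mixture with other cells is argued against by 80 genes that line 7 expresses and lines L and N lack, of which it kept a median of 1.807% (quartiles 0.647% and 2.86%). An exchange with another library of the series would need a partner among the other 5 lines that matches line 7 best, and 0 did. A mislabelled sample would be closest to another line, and its highest r, 0.987, was with the combination library of line N, above the lowest r within the other 5 lines, 0.964. It may also come from drug-treated cells, since its difference from the line N control correlated with the combination change of line L at r = 0.606, where line N itself gave r = 0.56. Its r with the line N control was 0.977. Its mean log2 CPM was 6.985 for the amino acid and ATF4 list and 1.15 for the interferon-stimulated list. These means were 6.81 and 1.30 in the line N combination library and 6.14 and 1.91 in the line N control. Both explanations can hold together and both stay open, and no biological one was tested.

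Mast cell genes rose and Hoxa9 fell with GSK591 in mutant lines 5 and 6. A few genes taking most of the counts is argued against, because the larger share of the mast cell list lowers other genes by a log2 change of -0.0392 at most, far less than the median fall of the genes of line M that lines L and N lack, -0.69 in line 5 and -0.92 in line 6. A mixed sample, with a larger share of cells like those of lines L and N, stays open: mixing their profile into the other mutant line's control gave changes that correlated with those observed at r = 0.717 in the lower of both lines. A change of state within the same cells could give the same values, and so could a dose of GSK591 that selects 1 kind of cell, neither of which was tested. The direction was not seen once line 7 was kept, where the control library described above enters. Among the drug libraries of line 7, the mast cell list was lowest with GSK591, at 1.40% of counts. It was at 1.89% with MS023 and 1.53% with the combination. In lines 5 and 6 the list was highest with GSK591, at 4.16% and 3.87%, so line 7 differed from them in its drug libraries too.

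The K562 combination departed from additivity at 2245 genes in WT and 287 in mutant cells. More spread between the mutant libraries is argued against by the noise-corrected SD of the departure, whose ratio of mutant to WT was 0.438 over genes with a mean log2 CPM of at least 3, from 0.259 without mutant L124 to 0.521 without WT L124. Whether a single replicate carried most of the difference in counts is not settled. The ratio of the WT to the mutant count was at least 1.661 in the fits that left out 1 replicate. It was lowest without WT L124, at 407 against 245 genes, and leaving out a WT library also lowers the power in WT. The mutant count rose to 504 without mutant L125. The SD ratio, at most 0.521 in these fits, shows that the departure stayed smaller in mutant cells. The difference itself passed at 1 gene, and at 0 without any 1 replicate but mutant L125, which gave 75. A smaller departure in mutant cells may be tied to the genotype, a hypothesis found and tested on the same libraries that stays open, since the splits given next do not exclude chance and other differences between the cultures were not tested.

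A comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. In K562 the genotypes without drug gave 4168 genes (highest other split 0) and the combination responses compared gave 224 (0). For MS023 and GSK591 the responses gave 0 each, in 10 of 10 splits. In WT cells MS023 gave 403 (1), GSK591 1229 (21) and the combination 8722 (0), and in mutant cells GSK591 gave 1404 (0) and the combination 6985 (0), each in 1 of 10 splits. MS023 in mutant cells gave 75 genes, while a split with both L125 libraries in 1 group and both L124 libraries in the other gave 1766, which points to a structure of these libraries by replicate (2 of 10 splits gave at least 75). The other 3 splits that part every same-numbered pair of these libraries gave 0, and the fit with the replicate block gave 178. Departure from additivity was compared with 100 splits of 12 libraries, and chance is not excluded: 5 gave at least the 2245 genes of WT cells (highest other 4720) and 11 the 287 of mutant cells (highest other 3097). The highest split in WT cells kept the 3 combination libraries together, as did one with 2657 genes in mutant cells, so these counts can hold the effect of the combination itself. The highest split in mutant cells made 3 libraries of L125 a group, which points to a structure of these libraries.

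In the principal mouse test the 6 drug comparisons gave 0 genes, so all 10 of 10 splits gave at least as many, with 4 as the highest other split for GSK591 in the mutant lines and 0 for the rest, and the 3 responses compared gave 0 with 0 elsewhere. The genotypes without drug gave 5 (0). Departure from additivity gave 0 in both genotypes, so all 100 splits gave as many. The highest split gave 8448 in the WT lines, with 3 libraries of line M as a group, and another gave 7288, with 3 libraries of line L as a group, which points to a structure of these libraries. A split that kept the controls of lines L, M and N together gave 8371. The highest in the mutant lines gave 0. With the line as a block, GSK591 in the mutant lines gave 548 genes and 2 of 10 splits gave as many. Of the other 3 splits that part every pair, the one that exchanged the libraries of line 7 gave 6834 and the rest 0, which points to that line. The combination in the mutant lines gave 86 (9), and without line 7 the WT lines gave 22 (1) for MS023, 33 (1) for GSK591 and 1654 (34) for the combination, all with too few splits.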

How the results depend on the processing

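The fits without line 7 or without only the library labelled mutant 7 control, each alternative run on them, and the contrast of additivity between the K562 genotypes were chosen only after the data were seen. K562 counts for the combination in either genotype and for the genotypes without drug stayed within 1.5 times of their value with RLE size factors, with no filter on low counts, with the replicate block and by DESeq2. RLE size factors in place of TMM moved 1 count by more, that of the MS023 responses compared in mouse without line 7, which became 0. With no filter on low counts, so that more genes were tested, the K562 counts were 707 for MS023 in WT, 320 for MS023 in mutant, 609 for departure from additivity in mutant, 7 for the MS023 responses compared, about 1.3e+02 for the GSK591 responses compared and 523 for the combination responses compared. DESeq2 gave K562 counts of 907 for MS023 in WT, 246 for MS023 in mutant, 577 for departure from additivity in mutant, 3 for the MS023 responses compared, 4 for the GSK591 responses compared and 451 for the combination responses compared. The cause of the DESeq2 differences was not tested. In mouse, no filter gave 2 for the genotypes without drug, and 366 for departure from additivity in mutant without line 7. By DESeq2 the mouse counts with all lines were 1 for GSK591 in WT, 2 for the combination in WT, 1 for MS023 in mutant, 57 for GSK591 in mutant, 13 for the combination in mutant, 2 for departure from additivity in mutant, 309 for the genotypes without drug, 1 for the MS023 responses compared, 2 for the GSK591 responses compared and 6 for the combination responses compared. Without line 7 DESeq2 gave 167 for MS023 in WT, 235 for GSK591 in WT, 2 for departure from additivity in WT, 141 for MS023 in mutant, 2018 for departure from additivity in mutant, 72 for the MS023 responses compared and 1553 for the combination responses compared.

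With the replicate block and all mouse lines, edgeR counts were 1 for MS023 in mutant, 548 for GSK591 in mutant and 86 for the combination in mutant. With that block and without only the library labelled mutant 7 control they were 11 for GSK591 in WT, 1138 for the combination in WT, 14 for MS023 in mutant, 5696 for GSK591 in mutant, 2181 for the combination in mutant, 1 for the MS023 responses compared, 2633 for the GSK591 responses compared and 104 for the combination responses compared. With the block and without line 7 they were 22 for MS023 in WT, 33 for GSK591 in WT, 1654 for the combination in WT, 18 for MS023 in mutant, 7061 for GSK591 in mutant, 2697 for the combination in mutant, 590 for departure from additivity in mutant, 1 for the MS023 responses compared, 5139 for the GSK591 responses compared and 495 for the combination responses compared. Without a block, leaving out only that library gave 358 for the genotypes without drug. The block changed no other mouse call of a comparison. In K562 the replicate numbers are shared by all groups, but nothing in the labels says that they mark a shared culture or day. Same-numbered libraries deviated together with r over 0.1 in 9 of the 18 pairs of WT libraries (r = 0.00654 to 0.234) and in 15 of the 18 pairs of mutant libraries (r = 0.0468 to 0.565). All 12 WT and 12 mutant libraries correlated best with a library of their own number, as a hint from the data. With the replicate block the K562 counts were 974 for MS023 in WT, 1863 for GSK591 in WT, 3408 for departure from additivity in WT, 178 for MS023 in mutant, 2131 for GSK591 in mutant, 531 for departure from additivity in mutant, 2 for the MS023 responses compared, 1 for the GSK591 responses compared, 436 for the combination responses compared and 2 for the departure from additivity compared.

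Leaving out 1 K562 replicate of 1 genotype gave WT counts of 24 to 1396 for MS023, 128 to 2394 for GSK591 and 407 to 4381 for departure from additivity. In mutant K562 cells the range was 8 to 166 for MS023, 101 to 3107 for GSK591, 4090 to 7400 for the combination and 18 to 504 for departure from additivity. Between the K562 genotypes it was 0 to 2 for the MS023 responses compared, 0 to 67 for the GSK591 responses compared, 20 to 235 for the combination responses compared and 0 to 75 for the departure from additivity compared. In mouse with all lines, leaving out 1 line gave 0 to 1 for GSK591 in mutant and 0 to 2686 for the genotypes without drug. Without line 7, leaving out 1 more line gave 0 to 31 for MS023 in WT, 0 to 42 for GSK591 in WT and 0 to 2642 for the combination in WT. For the mutant lines it gave 0 to 33 for MS023, 1698 to 7513 for GSK591, 296 to 3142 for the combination and 0 to 729 for departure from additivity. Between the genotypes it gave 0 to 29 for the MS023 responses compared, 815 to 4435 for the GSK591 responses compared and 3 to 1222 for the combination responses compared. Fewer libraries were left in these fits, and leaving out 1 of the 2 mutant lines left groups of 1 library, which was assumed to vary like the others.

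Of 190 values of named mouse genes, all but those without drug taken from the fit without line 7, 4 lost their call with RLE size factors, 2 by DESeq2 and 26 with no filter, each as 1 choice changed. Leaving out 1 line ended the call in 346 of the gene and line pairs tried and left it in 609. With line 7 kept, 156 lost their call without a block and 134 with the replicate block, 38 lost it with the block and without only the library labelled mutant 7 control, 182 lost it with no block and without only that library, and those named next changed sign. With all lines and no block, the log2 fold changes for GSK591 in the mutant lines had Mcpt2 at -2.10, Slco2b1 at -2.05, Elane at 0.019, Prss57 at 0.64, Bbc3 at -0.12, Sesn2 at -0.36, Eda2r at -0.22, Gzmb at -0.49 and Hoxa9 at 0.0059. For the combination in mutant, that fit had Mcpt2 at -0.72, Serpinb2 at -0.97, Bbc3 at -0.57, Trib3 at -1.27, Slc3a2 at -0.56, Gzmb at -0.62, Mcpt4 at -0.47, Vim at -0.17, Cdkn1a at -0.15 and Kit at -0.039. For MS023 in the mutant lines, that fit had Upp1 at -1.13 and Dnajc6 at 0.22. For departure from additivity in mutant, that fit had Prss57 at -0.83, Col18a1 at 1.60, Styk1 at 0.77, Aqp9 at 0.66 and Slco2b1 at 3.10. For the GSK591 responses compared, that fit had Mycn at -1.44 and Dusp4 at -0.12. For the combination responses compared, that fit had Serpinb2 at -1.16. With all lines and the replicate block, the log2 fold changes for GSK591 in the mutant lines had Mcpt2 at -1.14, Slco2b1 at -1.24, Bbc3 at -0.081, Sesn2 at -0.25, Gzmb at -0.76, Mitf at -0.091 and Hoxa9 at 0.23. For the combination in mutant, that fit had Mcpt2 at -0.029, Serpinb2 at -0.62, Bbc3 at -0.54, Trib3 at -1.20, Slc3a2 at -0.54, Gzmb at -0.90, Vim at -0.15, Cdkn1a at -0.22 and Kit at -0.18. For MS023 in the mutant lines, that fit had Upp1 at -0.85. For departure from additivity in mutant, that fit had Col18a1 at 0.39, Styk1 at 0.73, Aqp9 at 0.48 and Slco2b1 at 2.48. For the GSK591 responses compared, that fit had Mycn at -1.09. For the combination responses compared, that fit had Serpinb2 at -0.92. With no block and without only the library labelled mutant 7 control, the log2 fold changes for GSK591 in the mutant lines had Prss57 at 0.077. For MS023 in the mutant lines, that fit had Dnajc6 at 0.022. For departure from additivity in mutant, that fit had Prss57 at -0.27. With the block and without only that library no named gene changed sign. An estimated correlation ended the call in 26 of 28 list results and fry in 7. Camera turned the direction of 5 list results of the mutant lines once line 7 was kept. Its adjusted p without and with the block was 0.00262 and 0.00377 for the amino acid and ATF4 list with MS023, 0.559 and 0.901 for the mast cell list with GSK591, 0.152 and 0.229 for the amino acid and ATF4 list with the combination, 0.186 and 0.163 for the mast cell list with the combination and 0.156 and 0.229 for the interferon-stimulated list with the combination. Over genes with a mean log2 CPM of at least 3, the correlation between the genotypes was 0.731 for MS023 in K562, -0.255 for MS023 in mouse, 0.686 for GSK591 in K562, 0.907 for combination in K562 and -0.227 for combination in mouse.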

Other observations

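The choice of Terc in single drugs, of Fads2 in the WT lines and between the genotypes, and of Egr2 and Nr4a1 before treatment was made only after their values were seen. Terc was lower in each drug library than in the control of its line in L, M, N, 5 and 6. With MS023 alone it was at 7.02, 20.6 and 7.68 CPM in L, M and N against 12.3, 32.6 and 13.6 CPM without drug, and at 10.3 and 11.7 CPM in lines 5 and 6 against 20.9 and 21.6 CPM. With GSK591 alone it was at 6.33, 21.0 and 5.81 CPM in the WT lines and at 8.86 and 6.64 CPM in the mutant lines. By edgeR without line 7, with adjustment over all genes, only GSK591 in the mutant lines passed among the single drugs (-1.44 ± 0.23, adjusted p = 0.00029); the WT values were -0.77 (adjusted p = 0.139) with MS023 and -0.91 (adjusted p = 0.0776) with GSK591, and the mutant value was -0.95 (adjusted p = 0.146) with MS023. Departure from additivity was 0.027 ± 0.28 in WT and 0.27 ± 0.32 in mutant lines, so Terc passed no test against the sum.

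Genes of homologous recombination and the Fanconi anaemia pathway, which repair DNA breaks and crosslinks, fell with GSK591 in the mutant lines. Of 31 measured genes 20 fell and 3 rose, over all genes and adjusted over the list alone, with Palb2, the partner of Brca2, at -1.23 ± 0.20, Fancm at -1.12 ± 0.19 and Xrcc3 at -1.34 ± 0.24, while Nbn rose by 0.57 ± 0.10. Camera gave an adjusted p = 0.000312, and an adjusted p = 0.37 with an estimated correlation. This fall came beside that of DNA replication genes and a larger share of mast cell transcripts in the same libraries. With line 7 kept and the replicate block, Palb2 was at -0.55 ± 0.39 and did not pass (adjusted p = 0.5).

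Fads2, a desaturase of polyunsaturated fatty acids, fell with GSK591 in the mutant lines by 1.33 (SE 0.12, adjusted p = 5.2e-05) and with the combination by 1.09 (SE 0.12, adjusted p = 0.00031) in the fit without line 7. With all 3 mutant lines and the replicate block it fell by 1.46 (SE 0.15, adjusted p = 0.00242) and by 1.37 (SE 0.15, adjusted p = 0.0025). In that fit line 7 was measured against the library labelled mutant 7 control, so line 7 is not a sound further replicate. The level of Fads2 was 54.3 and 50.8 CPM in the line 5 and 6 controls and 22.6 and 19.2 CPM with GSK591. In the WT lines GSK591 gave -0.44 ± 0.10 (adjusted p = 0.0961), and the difference between the genotypes was -0.89 ± 0.16 (adjusted p = 0.00197), at different doses.

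Egr2 and Nr4a1 levels varied between lines before any drug. Egr2 was at 54.8 and 106.9 CPM in the L and N controls and at 0.877 CPM in M, and Nr4a1 at 86.9, 192.3 and 2.83 CPM in L, N and M. In the mutant controls of lines 5 and 6, Egr2 was at 37.3 and 8.99 CPM, and it reached 209.5 and 99.9 CPM with GSK591. Among the WT lines both genes were higher in the lines whose mast cell genes were high, as values with no test.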
